A study of Mus musculus with 9 samples.

How the data were processed

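The series holds 9 mouse testis samples from postnatal day 10, all of strain C57BL/6 per the labels. Of these, 3 are RNA-seq libraries labelled Lin28a knockout, 3 are RNA-seq libraries labelled wild type, and 3 are LIN28A CLIP samples, in which RNA bound to the LIN28A protein was recovered and sequenced. The CLIP samples were not analysed here. The labels do not say whether the libraries of a group came from separate animals.

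Reads were aligned with TopHat2 version 2.0.9 and the build was mm10, per the submitters' processing notes. The program that made the expression values is not given in the sources used here. The table has the column layout of a Cuffdiff gene table, with 1 row per RefSeq transcript accession. Per the file headers, the authors deposited FPKM (fragments scaled to transcript length and to the number of mapped fragments) in 2 columns, named case and control, together with a log2 ratio, a test statistic, a p-value, a q-value and a test status for each row. Each FPKM column holds a single value for its whole group, so no value per library was analysed, and no SD or n is given for any FPKM value below. The column named case was read as the knockout libraries and the column named control as the wild-type libraries, from the names of the columns alone. Because the level of Lin28a runs against that reading, both are called the column labelled case and the column labelled control throughout.

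The table had 29661 rows with 29660 distinct accessions. Its deposited log2 ratio was that of control over case in all 13586 tested rows with both FPKM values above 0, to within 5.01e-05, while every direction given below is case against control. Another 43 tested rows were listed at 0 FPKM in 1 column, where the deposited ratio is a placeholder and no fold is given. The status was OK in 13629 rows, NOTEST in 12978, FAIL in 2896 and LOWDATA in 158. The q-values the authors deposited were those of a Benjamini-Hochberg adjustment of their p-values over the 13629 rows with status OK, to within 2.26e-06. How the replicate libraries entered the authors' test is not given in the sources used here. Rows with status FAIL carry FPKM values but no usable p-value, since all 2896 are listed at p = 1 by the authors.

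Symbols were taken by accession from a RefSeq gene table of assembly GRCm38.p6 for 29067 of the 29660 accessions (98.0%), and otherwise from the names in the table. Positions are those of the deposited table. Its starts were read as counting from 0, because 13898 of them lay exactly 1 below the start of the gene in the RefSeq table and 986 were equal to it, and 1 was added to each start given here. The coordinates of the RefSeq table were used for nothing else. There were 23386 symbols, of which 3948 had more than 1 row.

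The test fixed before the data were examined, limma on log2(FPKM + 1) of 6 libraries, needs values per library and could not be run; nor could camera, fry, the exact permutation test of Lin28a, or any fit that leaves out or weights a library. Calls of single rows are therefore the authors' own, at a q-value under 0.05. Gene lists were described without a test. FPKM was summed over all rows of a gene, genes with a mean FPKM of at least 1 were kept (12663 genes, 11645 of them with an authors' p-value), and the difference of log2(FPKM + 1), case minus control, was taken. The pseudocount of 1 makes this difference smaller than the true change for genes at low FPKM. The median of each list was set among the medians of 10000 random lists of the same size, drawn from genes outside the list and matched on 20 bins of mean expression. A list is called outside when its percentile is under 2.5 or over 97.5, that is, outside the central 95% of these random lists. The percentile describes these 2 columns and is not a p-value over animals. In data simulated for this comparison from the 12663 genes, 4 of 100 lists of 45 unshifted genes lay outside. With their genes lowered by 0.1 on the log2 scale, 99 of 100 lists did so. The simulated lists were random genes with shuffled differences, so their members did not vary together. Genes of the same cell type or pathway can, so the rate of 4 in 100 need not hold for the lists described here. List members were counted by the authors' p-value of their row with the highest FPKM, adjusted over all rows and, separately, adjusted over the list alone.

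Of 24 gene lists fixed before the data were examined, 22 had at least 5 members to analyse. The mitochondrial genome list had none of its 13 genes in the table, and the skeletal muscle list had 3 members at a mean FPKM of at least 1, so neither was described. The genes named were fixed by rule: Lin28a and Lin28b, the 10 largest rises and falls past the threshold or, where fewer passed, those with the smallest unadjusted p-value up to 5 in a direction, and from each list the 3 members with the smallest p-value. The part of the rule that asks for non-overlapping libraries could not be applied. Genes named outside this rule are said to be so, and some genes that the rule names are not reported here.

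The depth of each library is unknown. In 58 short olfactory and vomeronasal receptor rows above 0 in the column labelled case, FPKM times locus length in kilobases was a whole multiple of the smallest such value in 13.8% of rows, to within 0.1 of a multiple, so the values held no common step from which reads could be counted. Alternatives to the pseudocount, the filter on low values, the scaling, the treatment of several rows per gene and the threshold were run; the closing section gives their effect. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.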

Results

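Testis mRNA at postnatal day 10 was profiled in 3 libraries labelled Lin28a knockout and 3 labelled wild type. LIN28A is an RNA-binding protein that blocks maturation of let-7 microRNAs and binds mRNAs, and in the postnatal testis it marks undifferentiated spermatogonia. At this age the most advanced germ cells have entered the prophase of the first meiotic division. The table analysed gives 1 pooled FPKM value per group and the authors' test between them, so no spread between libraries can be set beside any value, and the depth of the libraries is unknown. FPKM summed to 328508 in the column labelled case and 325735 in the column labelled control, with medians of 8.94 and 8.72 over the 13629 tested rows. The comparison asks which transcripts differ in level when Lin28a is lost, in a study whose title concerns the translation of meiotic transcripts.

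Lin28a (NM_145833; mm10 chromosome 4, 134003330 to 134018816), the targeted gene, was at 23.4 FPKM in the column labelled case and 8.82 FPKM in the column labelled control of the authors' deposited table. It was thus 2.66-fold higher in the column read as the knockout, with p = 5.62e-07 and q = 0.00191 in the authors' deposited table. This goes against that label, and every direction below rests on the column names alone. Lin28b, the paralog of Lin28a, stood at 6.95 and 6.59 FPKM, with p = 0.794 in the authors' deposited table.

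In all, 7 rows of the authors' deposited table passed a q-value of 0.05, of which 6 were higher and 1 was lower in the column labelled case. Besides Lin28a, the higher ones were Erdr1, Zfp949, Mid1, Plbd1 and Morf4l2. Erdr1 (NM_133362; chromosome Y, 90785442 to 90816465), a gene of the pseudoautosomal region, was at 427 FPKM in the column labelled case and 71.8 FPKM in the other, a 5.94-fold difference with q = 3.03e-12 in the authors' deposited table. Its row carries the names of 2 genes, so reads from near-identical copies may be split or joined there, and its level is uncertain. Plbd1 (NM_025806; chromosome 6, 136612071 to 136661893), a phospholipase B-like protein, was at 13.1 and 3.20 FPKM, 4.11-fold higher with q = 0.00273 in the authors' deposited table. Pcsk1n (NM_013892; chromosome X, 7919822 to 7928607), which encodes an inhibitor of the prohormone convertase PCSK1, was the single lower row, at 5.19 against 17.8 FPKM, or 3.42-fold lower with q = 0.00496 in the authors' deposited table.

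The 3 other called rows each belong to a gene with more than 1 row. Mid1 (NM_010797; chromosome X, 169685247 to 169990797), a microtubule-associated ubiquitin ligase, was at 9.99 and 1.95 FPKM, 5.14-fold higher with q = 7.33e-04 in the authors' deposited table, and summed over its 2 rows it was 2.72-fold higher. The called row of Zfp949 (NM_001163061; chromosome 9, 88548020 to 88571086), a zinc finger gene, was at 9.78 FPKM and listed at 0 in the column labelled control, with q = 1.68e-06 in the authors' deposited table. Its other row was at 2.26 and 4.07 FPKM, and the 2 rows together were 2.96-fold higher in the column labelled case. Morf4l2 (NM_001168226; chromosome X, 136732948 to 136803361), a chromatin protein, had its called row at 30.7 and 9.63 FPKM, 3.19-fold higher with q = 0.0132 in the authors' deposited table. Summed over its 7 rows it was at 204 and 214 FPKM, so the direction turned at the level of the gene.

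**Figure D1:**
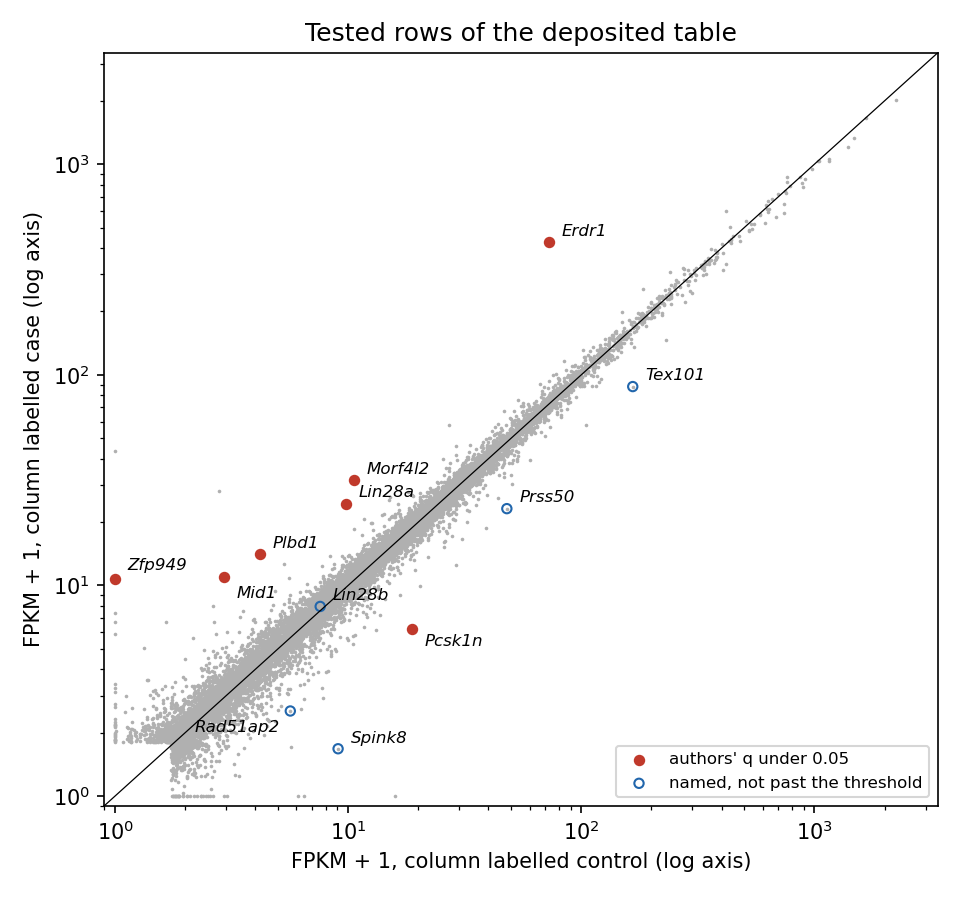
FPKM + 1 of the 13629 tested rows in the column labelled control (x, log axis) and the column labelled case (y, log axis), with the line of equal values; each point is 1 row, with no replicate values. Filled red points are the 7 rows past the authors' q of 0.05. Of these, Erdr1 lies highest at 427 against 71.8 FPKM, and only Pcsk1n lies below the line. Open blue circles are the rows of Tex101, Prss50, Spink8, Rad51ap2 and Lin28b, which did not pass.

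After Pcsk1n, the lower rows with the smallest p-values did not pass the threshold and are given as values. Tex101, a germ cell surface protein needed for sperm function, was at 87.0 FPKM in the column labelled case and 165 FPKM in the column labelled control, with p = 1.95e-04 and q = 0.292 in the authors' deposited table. Prss50, a testis serine protease, was at 22.2 and 47.0 FPKM, with q = 0.292 in the authors' deposited table. Spink8, of a family of serine protease inhibitors, was at 0.677 and 8.05 FPKM, and Rad51ap2 at 1.53 and 4.65 FPKM, both with q = 0.492 in the authors' deposited table. At an unadjusted p under 0.05, 88 rows were higher and 86 lower in the column labelled case, or 1.28% of the tested rows, and the median p was 0.731. A test with no differences at all would put about 5% of p-values there if they were evenly spread, so the authors' p-values were concentrated near 1.

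Genes of meiotic prophase were lower as a group in the column labelled case. Of all genes analysed, 60.8% were higher in that column, which is the share to set beside the counts of list members below. Of 50 genes on the list, 45 were analysed and 43 of these were lower, with a median log2(FPKM + 1) difference of -0.44. That median lay below all 10000 matched random lists, whose central 95% ran from -0.01 to 0.08. By the authors' p-values, 0 of the 41 members with one passed over all rows, 14 were under 0.05 unadjusted, all of them lower, and 9 passed when adjusted over the list alone. These 9 were Tex101, Meiob, Rad51ap2, Hormad1, Sycp2, Dmc1, Fbxo47, Ugt8a and Sycp1. Of the meiotic genes given by name, Hormad1, Sycp2, Dmc1, Fbxo47, Sycp1, Sycp3, Trip13 and Mlh3 lie outside the naming rule and were chosen after their values were seen. Meiob, a single-strand DNA-binding protein of meiotic recombination, was at 1.92 and 6.82 FPKM, with p = 6.01e-04 in the authors' deposited table and an adjusted p of 0.00822 over the list alone. Dmc1, the meiotic recombinase, was at 14.2 and 24.9 FPKM in the authors' deposited table, with an adjusted p of 0.0386 over the list alone. Hormad1, a protein of unsynapsed chromosome axes, was at 15.6 and 29.8 FPKM (0.0334 over the list alone), and Sycp1, of the central region of the synaptonemal complex, was at 38.5 and 59.1 FPKM (0.0464 over the list alone), in the authors' deposited table. Sycp3, of the chromosome axis, was at 69.2 and 125 FPKM in the authors' deposited table, where the status of its row is FAIL and no p-value can be read. Trip13 and Mlh3 were the 2 members with higher values, at 24.8 and 23.3 FPKM and at 5.99 and 5.61 FPKM in the authors' deposited table. The 5 genes of the list outside the table were not analysed here.

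**Figure D2:**
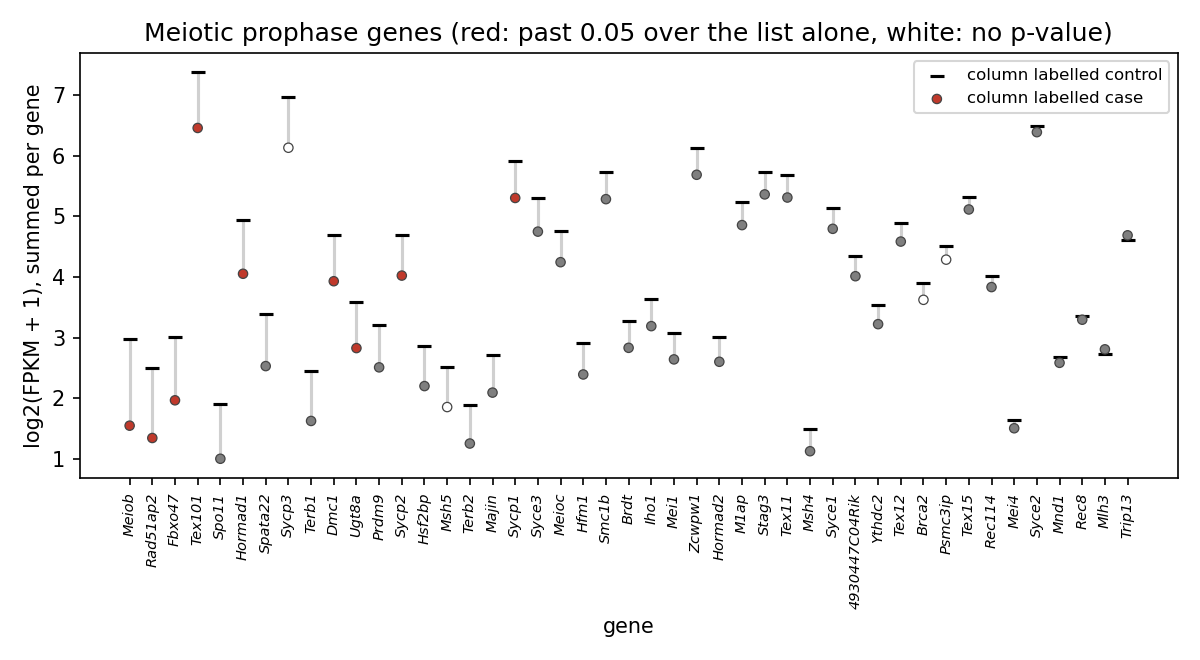
log2(FPKM + 1), summed over the rows of each gene (y), for the 45 analysed genes of the meiotic prophase list (x), ordered by difference; dashes are the column labelled control and circles the column labelled case, 1 pooled value each. Red circles are the 9 genes past 0.05 over the list alone, white circles have no p-value, and 43 of the 45 circles lie below their dash.

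Other germ cell groups differed by less. Germ cell core and piRNA pathway genes had a median difference of -0.10, below all 10000 random lists, with 19 of 24 lower, 0 passing over all rows and 1, Tex101, adjusted over the list alone. Without the 2 genes that the meiotic list also holds, the median of the remaining 22 was -0.07. Mov10l1, an RNA helicase of the piRNA pathway, was at 35.0 and 41.9 FPKM, and Tex14, needed for intercellular bridges, at 23.9 and 28.0 FPKM in the authors' deposited table. Differentiating spermatogonia genes had a median of -0.09 at percentile 0.04, with 11 of 16 lower and 0 passing over all rows or over the list alone; Stra8, a retinoic acid target needed to enter meiosis, was at 68.1 and 86.3 FPKM in the authors' deposited table (p = 0.164), and Esx1 at 18.0 and 23.3 FPKM. Undifferentiated spermatogonia genes were inside the range, with a median of 0.04 at percentile 47.2, 13 of 20 higher and 0 passing either adjustment; Id4, a stem cell marker, was at 4.94 and 6.61 FPKM, Bcl6b at 4.37 and 3.49, and Utf1 at 1.71 and 2.56 in the authors' deposited table. The pachytene and spermatid list had 8 of 30 genes at a mean FPKM of at least 1, with a median of -0.27 below all 10000 random lists and 0 passing either adjustment. Meig1 was at 5.84 and 9.13 FPKM, Mybl1 at 4.41 and 6.01 and Ybx2 at 5.48 and 7.16 in the authors' deposited table. With no filter on low values, the median of 27 genes of that list was 0.0023 at percentile 26.1, so its place outside the range held for the filtered genes.

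Markers of Leydig, peritubular and stromal, and endothelial cells were higher in the column labelled case, beside the lower meiotic genes. Cholesterol biosynthesis genes were higher as well. Leydig cell genes had a median difference of 0.24, above all 10000 random lists, with 14 of 16 higher. Hsd17b3, which makes testosterone from androstenedione, was at 38.7 and 24.6 FPKM (p = 0.0302), Cyp11a1, the side-chain cleavage enzyme that starts steroid synthesis, at 45.7 and 32.4, and Cyp17a1, a later enzyme of the same path, at 26.0 and 17.8 in the authors' deposited table. Peritubular myoid and stroma genes had a median of 0.22, above all 10000 random lists, and all 22 were higher, among them Col1a1 at 69.9 and 53.9 FPKM, Tcf21 at 55.5 and 41.5, and Gli1 at 8.62 and 6.63 in the authors' deposited table. Endothelial genes had a median of 0.20 at percentile 99.8, with 11 of 13 higher; the vascular receptor gene Kdr was at 4.14 and 3.27 FPKM, Eng at 7.84 and 5.41 and Robo4 at 3.14 and 2.28 in the authors' deposited table. Cholesterol biosynthesis genes had a median of 0.15 at percentile 99.99, with 21 of 23 higher, among them Sqle at 26.7 and 20.8 FPKM and Cyp51 at 14.0 and 11.0 in the authors' deposited table. In these 4 lists, 0 members passed over all rows and 0 over the list alone.

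Sertoli cell genes, by contrast, were inside the range, with a median of -0.01 at percentile 7.13 and members on both sides. Rhox5 and Tsx, both on chromosome X, were at 8.90 and 19.3 FPKM (p = 0.0254) and at 6.27 and 12.7 FPKM (p = 0.0595), and Cst9 at 596 and 416 FPKM (p = 0.0593) in the authors' deposited table. Macrophage and immune genes had a median of -0.12 at percentile 0.01, with 14 of 18 lower; Lyz2 was at 31.9 and 45.6 FPKM and H2-Ab1 at 1.70 and 3.07, but Cd74, of antigen presentation, was at 5.70 and 1.66 (p = 0.00524) in the authors' deposited table. The epididymis and duct epithelium list had 6 of 16 genes to analyse, with a median of -0.37 below all 10000 random lists. Crisp1, a secreted epididymal protein, was at 0.261 and 2.27 FPKM, Epcam, which spermatogonia also express, at 32.4 and 43.4, and Cst8 at 17.6 and 9.65 in the authors' deposited table; Crisp1 alone passed over the list, with an adjusted p of 0.0154. Adipose genes (5 analysed) had a median of -0.05 at percentile 11.2, with Lpl, lipoprotein lipase, at 25.3 and 14.1 FPKM and an adjusted p of 0.0223 over the list alone, Pparg at 1.77 and 2.79 and Cidea at 30.5 and 36.5 in the authors' deposited table. Red blood cell genes (7 analysed) had a median of 0.05 at percentile 72.6, with Hba-a1 at 667 and 629 FPKM and Hbb-b2 at 18.2 and 23.4 in the authors' deposited table. No member of these 5 lists passed over all rows, and in the Sertoli, macrophage and red blood cell lists 0 passed over the list alone.

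**Figure D3:**
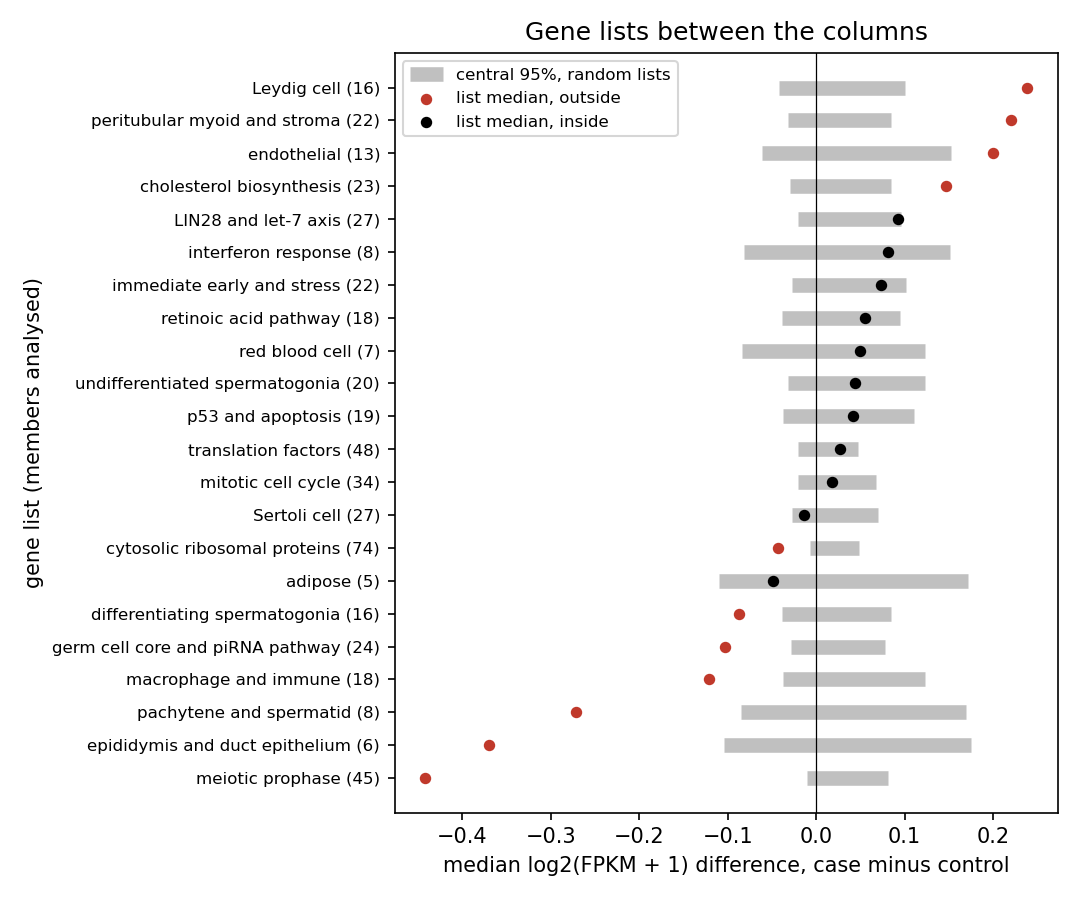
Median log2(FPKM + 1) difference, case minus control (x), of the 22 gene lists analysed (y, members analysed in parentheses); grey bars are the central 95% of 10000 matched random lists, not an error over animals. Of the 22 medians, 7 lie below and 4 above their bar (red), from -0.44 for meiotic prophase to 0.24 for Leydig cells.

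Genes tied to LIN28 function differed little. The LIN28 and let-7 axis list, which holds let-7 targets such as Trim71, had a median of 0.09 at percentile 96.7, just inside the range, with 19 of 27 higher. Arid3b was at 10.7 and 8.71 FPKM and Igf2bp2 at 3.80 and 2.91 in the authors' deposited table, and 0 of its members had p under 0.05. It lay outside with quantile normalization (0.07, percentile 98.1) and with no filter (0.09, percentile 97.6). Cytosolic ribosomal protein genes had a median of -0.04, below all 10000 random lists, with 51 of 74 lower. Rpl29 was lower, at 145 and 230 FPKM (p = 0.00917), Rps2 was higher, at 307 and 240, and Rps28 was listed at 0 in the column labelled case and at 15.0 in the other, in the authors' deposited table. Ribosomal protein genes have many processed pseudogenes, which can take their reads, so these values are uncertain. Translation factor genes were inside the range, with a median of 0.03 at percentile 78.9, where the median over all 12663 genes was also 0.03, and with Eif3f at 116 and 103 FPKM, Eif4h at 104 and 89.0 and Eif4a1 at 38.6 and 45.5 in the authors' deposited table.

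The 5 remaining lists were inside the range. As in the 3 lists above, 0 of their members passed over all rows and 0 over the list alone. Mitotic cell cycle genes had a median of 0.02 at percentile 39.2. Top2a was at 77.3 and 93.6 FPKM, Ccna2 at 42.3 and 36.5 and Ube2c at 45.3 and 38.4 in the authors' deposited table. Retinoic acid pathway genes had a median of 0.06 at percentile 79.7, with Aldh1a2, a retinoic acid synthesis enzyme, at 52.2 and 42.4 FPKM and Cyp26a1, which degrades retinoic acid, at 1.19 and 2.28 in the authors' deposited table. The medians were 0.04 for p53 and apoptosis genes (percentile 55.2), 0.07 for immediate early and stress genes (87.1) and 0.08 for interferon response genes (78.5). Sesn2 was at 15.2 and 19.0 FPKM, Bak1 at 8.68 and 7.11, Fos at 1.98 and 3.22, Hspb1 at 72.2 and 55.2 and Bst2 at 46.8 and 38.8 in the authors' deposited table, all with p above 0.05. Immediate early and stress genes lay outside at a mean FPKM of at least 5 (0.13, percentile 99.8).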

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

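The counts of called rows, 6 higher and 1 lower in the column labelled case, changed by no more than 1.5 times with the tested rows filtered at a mean FPKM of 1 or 5 and adjusted again, with every row of the table adjusted, at an adjusted p under 0.10, and at a fold of at least 1.5. Of the alternatives added after seeing the data, an unadjusted p under 0.05 gave 88 higher and 86 lower rows, as the threshold itself implies, and 5 higher and 1 lower calls stayed at 1.5-fold after a gene's rows were summed. The Lin28a difference of 1.32 moved by under 0.1 on the log2 scale under each alternative run. The meiotic prophase median of -0.44 stayed below the central range under all 9 alternatives, between -0.51 and -0.42, among them one added after seeing the data that left out the 3 members held by another list. Against 11 of 22 lists outside, there were 10 of the 18 lists left at a mean FPKM of at least 5 (9 of them outside before), 11 of 23 with no filter (10 of them outside before), 12 of 22 with quantile normalization and 11 of 22 under each other alternative. Of 173 list medians under alternatives, 169 stayed on their side of the range with direction kept where they were outside. Another 3 came to lie outside. The remaining 1, that of pachytene and spermatid genes with no filter, changed sign to 0.0023. It came to lie inside the range (percentile 26.1), where genes near 0 FPKM enter the list. Of 55 values of 11 other named genes, 14 moved by over 0.1, mostly genes of low FPKM with a smaller pseudocount, and 1 reversed: Morf4l2, at -0.069 with its rows summed, where its other rows outweigh the called one. Median-of-ratios rescaling divided the columns' ratio by 1.03. Not run, for lack of values per library: eBayes without a trend or robust, arrayWeights, leaving out each library, camera with an estimated correlation, fry, and other splits of the samples. The pseudocount and scaling cannot move the authors' calls. No paired analysis was possible because each group is 1 pooled column. Depth is unknown and sets no interval here.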

Other observations

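Genes in this paragraph were chosen after their values were seen. Spp1, which encodes the secreted protein osteopontin, had the smallest p-value among the rows that did not pass, at 56.7 FPKM in the column labelled case and 26.0 in the other, with q = 0.183 in the authors' deposited table. Ly6k, which forms a complex with TEX101 on germ cells, was at 17.7 and 38.0 FPKM (p = 0.00417), Dpep3, another partner of TEX101, at 25.0 and 43.0 (p = 0.00493), and Ccnb3, a cyclin of early meiotic prophase, at 3.86 and 7.45 (p = 0.00504) in the authors' deposited table. Scd1, a fatty acid desaturase, was at 3.58 and 1.68 FPKM (p = 0.00880), and Cbln4 at 2.19 and 0.487 (p = 3.91e-04) in the authors' deposited table. None of these passed a q-value of 0.05.

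Of the 7 called rows, 4 lie on chromosome X or Y, which hold 4.56% of the tested rows. They are Erdr1, Mid1, Morf4l2 and Pcsk1n. Morf4l2 was not higher with its rows summed, and the level of Erdr1 is uncertain, as given above. Erdr1 lies in the pseudoautosomal region, and Mid1 lies across its boundary. The median difference of 567 rows on chromosome X was -0.01, against 0.03 elsewhere. Around Lin28a, 11 other tested rows at a mean FPKM of at least 1 lie within 250 kb on either side, and 2 of them (18.2%) differed by over 1.5-fold on the log2(FPKM + 1) scale, against 2.16% of all 12712 such rows. These, chosen with Dhdds after their values were seen, were Hmgn2, 35.3 kb away, at 56.9 and 104 FPKM (p = 6.87e-04), and Cd52, 74.7 kb away, at 2.27 and 6.73 (p = 0.0507) in the authors' deposited table, while Dhdds, which lies between Hmgn2 and Lin28a, was at 14.6 and 16.0. Hmgn2 has many processed pseudogenes, so its level is uncertain. There were 26 tested rows listed at 0 in 1 column and at 1 FPKM or more in the other, of which 17 belong to genes with more than 1 row and 18 had an unadjusted p under 0.05.

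Except for quantile normalization and the setting with no filter, the tests in the 3 paragraphs that follow were chosen after the results were seen. Lin28a was 2.66-fold higher in the column labelled case, against its label. More undifferentiated spermatogonia, which express Lin28a, do not account for it: their list had a median difference of 0.0435 (robust SD of members 0.21) where the Lin28a difference was 1.32. Columns with exchanged labels may explain it. Then the let-7 target genes, which depend on LIN28 proteins, would be higher in the column labelled case. Their list stood at percentile 96.7, inside the central range. It lay above the range with no filter (97.6) and with quantile normalization (98.1). Under each other alternative it was inside, at percentiles from 95.3 to 97.0. Correct labels were predicted to put the list below the central range, and no setting put it there. Exchanged labels were predicted to put it above, and most settings left it just inside. With neither prediction met throughout, exchanged and correct labels cannot be told apart by this list. An altered Lin28a transcript that accumulates in the knockout also stays open, because the table holds 1 Lin28a row, and the part of the gene that was removed is not given in the sources used here. If the labels are exchanged, each direction above turns, and the knockout column would still hold Lin28a, at the lower of its values.

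Meiotic prophase genes were lower in the column labelled case. A scaling difference that varies with expression level did not account for this, since their median was -0.48 after quantile normalization, below all 10000 random lists, and a single factor for a column moves a list and its random lists alike. A lower share of all germ cells would lower the germ cell core genes outside the meiotic list by as much, but their median was -0.0687 (robust SD 0.14), and dilution by Leydig, stromal and endothelial cells, whose markers were higher (macrophage markers were lower), would lower undifferentiated spermatogonia genes as well, but their median lay 0.49 above the meiotic one (robust SD 0.21), so neither is the whole cause. A less advanced first wave of meiosis may be, as a hypothesis. The pachytene and spermatid median lay 0.17 above the meiotic one (robust SD 0.26). That list cannot decide it, because only 8 of its 30 genes reached a mean FPKM of 1. Its median was also 0.0023 with no filter on low values. An effect of genotype stays open and untested. With 1 pooled value per group, no other split of the libraries could show how often chance gives such a list.

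Calls were made on single RefSeq rows, so fragments assigned to another row of the same gene could produce a call. For Morf4l2 the values are consistent with this, since the summed FPKM of its rows differed by 1.05-fold, in the other direction. For Zfp949 and Mid1 the summed FPKM still differed by 2.96-fold and 2.72-fold in the direction of the called row. This argues against moved fragments as the whole cause only if the rows are of like length, which was not checked. FPKM is scaled to transcript length, so fragments moved between rows of unlike length change the sum. No biological explanation was tested for these rows.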
